A study of Mus musculus with 24 samples.

How the data were processed

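RNA from the livers of 24 female mice was hybridised to 1-colour Agilent mouse arrays, 1 array per mouse, in 4 groups of 6. Per the labels, total RNA was extracted with TriZol and labelled with Cy3. Per the file headers, the scanner files were made by Agilent Feature Extraction 10.10.1.1, and each deposited file gives the intensity of every spot. The processed intensity had been background-subtracted and spatially detrended within the array by that program, per the file headers, and was not normalised between arrays. A deposited table holds the authors' own log2 values for 33417 of the 56605 non-control probes. The submitters' processing notes name limma. The medians of the table's 24 columns were all about 7.86 and the quartiles were nearly equal, as after quantile normalisation between arrays, and genes were not centred. The filter and background step behind it are not given in the sources used here. Each column correlated best with the scanner values of its own array for 24 of 24 arrays (r of deviations from probe means 0.905).

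Main values were log2 of the processed signal minus each array's 75th percentile over the non-control spots. The 59305 spots included 64 to 121 per array marked as outliers, which were set to missing, and 0 saturated spots. Spots of a probe were averaged. A probe was tested where it was well above background on every unmarked array of at least 1 group and had at least 4 values in each group. This kept 33417 probes and left out 23188. Of the tested probes, 32012 were also among the probes of the authors, and 1405 were exclusive to each set. A gene was its tested probe with the highest mean, which gave 22088 genes, 7451 of them with more than 1 tested probe. Probes were named through their RefSeq accession in a table of the GRCm38.p6 assembly for 32994 probes (58.3%) and 14782 tested genes, and by the file's own name otherwise. Coordinates are those of the files, build mm9.

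The 5 comparisons were fitted with limma 3.58.1 in R 4.3.3, and files were read with the data.table package (version 1.17.8). All 24 arrays entered 1 fit of 4 group means without covariates, tested by lmFit and eBayes with Benjamini-Hochberg adjustment and called at adjusted p under 0.05. They were FB1 in WT, FB1 in KO, KO against WT without and with FB1, and the difference of the FB1 effects. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Where a probe was not well above background on any array of a group, the fold is a lower bound. It was computed from the bright group's mean and, per array of the dim group, the higher of the probe's own signal and the lowest signal among probes well above background. Where 3 or fewer arrays of a group were well above background, a value with the dim arrays raised to that floor stands beside the fitted one.

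The 31 gene lists, the named-gene rule, the tests of the comparisons and the alternatives listed here were fixed before the data were examined, while some tests of explanations were chosen later, as stated with them. The lists were LXR targets, fatty acid and triglyceride synthesis, cholesterol, bile acids, sphingolipids, xenobiotic enzymes, NRF2, unfolded protein response, p53, cell cycle, acute phase, chemokines, interferon, matrix, PPARα, gluconeogenesis and amino acid catabolism, circadian clock, female-biased, male-biased, fetal, and markers of hepatocytes, cholangiocytes, resident macrophages, recruited monocytes, neutrophils, T and NK cells, B and plasma cells, sinusoidal endothelium, stellate cells, erythroid cells, and pancreas and adipose tissue. Of their 668 symbols, 661 matched a gene on the array. Some genes stand in more than 1 list, such as Lyz2 and Lgals3. Each list was tested with camera at a preset correlation of 0.01 and adjusted over the lists of a comparison, with an estimated correlation as an alternative. Of 84 list calls over all comparisons, 1 held with it. Named genes were the 8 largest called rises and falls per comparison, the 3 called members of each list with the smallest p or, in a list without a call, the 1 with the smallest p, and always Nr1h3, Nr1h2 and the ceramide synthase genes Cers2, Cers4, Cers5 and Cers6. Of the other ceramide synthase genes, Cers3 was well above background on 0 arrays and Cers1 had 0 probes under that symbol. Not every gene the rule allows is named, some results are not reported here, and the choice among them was made with their values known. Mirg, Rian, the FB1 effects on Meg3 and the value of Dlk1 between genotypes were chosen outside the rule after their values were seen.

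Alternatives were quantile normalisation, normexp background correction with an offset of 50, the authors' values, 2 other filters on dim probes, outlier spots kept, the mean of a gene's probes, slide or replicate number as a block, each slide alone, the groups of a comparison alone, an intensity trend, array weights, a 1.5-fold or stricter threshold for counts of genes, and leaving out each array. Tested on simulated data over 22088 genes, the fit recovered 63 of 100 genes changed 1.5-fold and 96 of 100 changed 3-fold for FB1 in WT. For FB1 in KO it recovered 63 and 98, for KO against WT without FB1 52 and 93, with FB1 69 and 94, and for the difference of effects 50 and 89. The noise was independent between genes and few genes were changed, drawn anew for each comparison. Differences between these counts may therefore come from the genes drawn, and real shares may differ. The number of arrays limits the precision of each value.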

Results

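Liver RNA of 24 female mice was measured on 1-colour Agilent expression arrays. Fumonisin B1 (FB1) is a mycotoxin that inhibits ceramide synthases, the enzymes that join a fatty acid to a sphingoid base. LXRα and LXRβ are oxysterol receptors encoded by Nr1h3 and Nr1h2, and the KO mice lack both. The mice were 8 weeks old, of a sv129/C57 background, and received water or FB1 at 10 mg/kg per day for 1 month. There were 4 groups of 6 mice each, here called WT control, WT FB1, KO control and KO FB1, with 1 array per mouse. On each array 58.7% to 64.5% of the 59305 non-control spots were well above background, and the 75th percentile of the processed signal lay between 490 and 685. The arrays lay on 3 slides of 8, each with 2 arrays of every group. Arrays of the same group correlated at 0.984 to 0.994 over genes, and no pair held identical values. The number of arrays limits the precision of every value below. Values after ± are standard errors of a log2 difference between group means of 6 arrays each, unless stated. They come from 1 spread per gene shared by all 24 arrays, not from the compared groups alone. Adjusted p values of single genes are from limma.

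The design asks what FB1 changes in the liver, what loss of both receptors changes, and whether the response to FB1 depends on them. The deleted genes were examined first. Nr1h3 was read by 2 probes. The probe used, on chromosome 2 at 91024250 to 91024309 (mm9), lay between 4.76 and 5.06 in the 6 WT control arrays and between 4.71 and 4.95 in the WT FB1 arrays, in log2 units relative to each array's 75th percentile. In KO control arrays it lay between -5.13 and -3.98. In KO FB1 arrays it lay between -5.12 and -2.56, and the highest of these was replicate 6. Its log2 difference between KO and WT was -9.45 ± 0.29 without FB1 (adjusted p = 4.6e-17) and -9.17 ± 0.29 with FB1. The other Nr1h3 probe, at 91024435 to 91024494, differed by -9.19 ± 0.22 without FB1. For Nr1h2 the probe on chromosome 7 at 51805013 to 51805072 lay between 4.02 and 4.34 in all WT arrays and between 0.31 and 0.80 in all KO arrays. Its difference was -3.66 ± 0.08 without FB1 (adjusted p = 2.18e-20) and -3.62 ± 0.08 with FB1. A further tested Nr1h2 probe, at 51807934 to 51808069, was well above background on all 6 arrays of each group and did not pass the test (0.20 ± 0.09, adjusted p = 0.152), and the remaining one was not well above background in any whole group. Which part of each gene was deleted is not given in the sources used here, and a probe outside that part checks nothing. FB1 changed neither gene's signal past the threshold in WT (Nr1h3 -0.10 ± 0.29, adjusted p = 0.894; Nr1h2 -0.069 ± 0.08, adjusted p = 0.668) or in KO (0.18 ± 0.29, adjusted p = 0.657; -0.026 ± 0.08, adjusted p = 0.808). The shared error of Nr1h3 comes largely from the dim KO arrays. Its SD was 0.53 in KO control and 0.91 in KO FB1 arrays, against 0.13 in WT control and 0.10 in WT FB1 arrays.

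**Figure D1:**
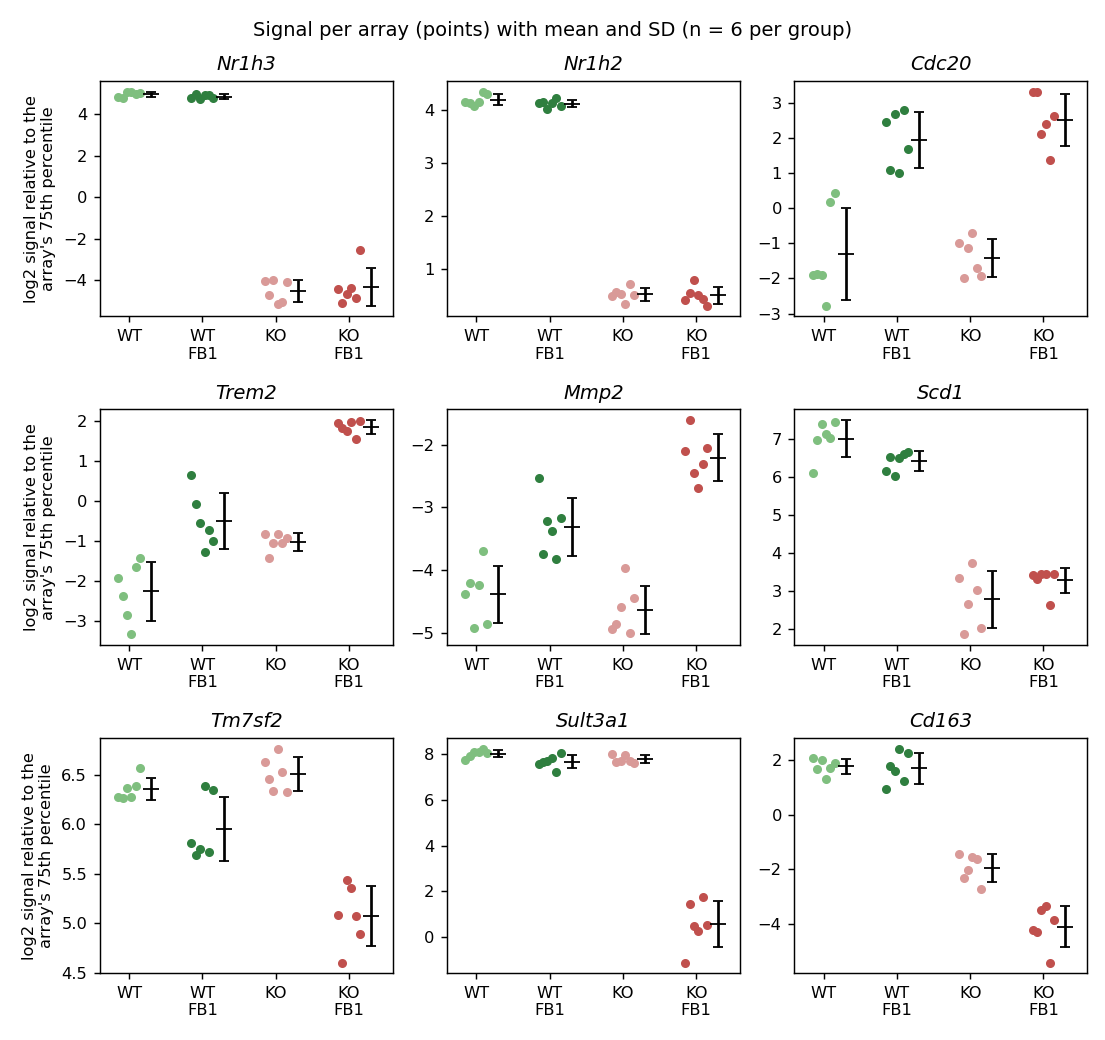
Signal of 9 genes per array (points, n = 6 per group) with the group mean and SD, in log2 units relative to the array's 75th percentile. Nr1h3 and Nr1h2 separate the genotypes, and Sult3a1 lies near 8 in 3 groups and at a mean of 0.55 in KO mice given FB1.

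FB1 in WT mice raised the median of the cell cycle list more than that of any other list examined, though this list call was lost with an estimated correlation. Of the 39 tested cell cycle genes, 32 rose and 0 fell, with a median log2 change of 1.79. Genes of the extracellular matrix and markers of recruited macrophages rose in smaller numbers, and the 35 sphingolipid genes yielded a single call, Kdsr. In all, 638 of 22088 genes changed, 456 higher and 182 lower, and 417 of them by at least 1.5-fold. For the 33 genes named as called in this comparison, Meg3 and Mirg included, each of the 6 FB1 arrays lay beyond the mean of the WT controls, but these genes were chosen for being called. Over all genes with a value on every array of both groups, the groups did not overlap for 513 of 22064 (2.33%, where chance gives 0.216%).

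The mitotic genes were among the largest rises. Ckap2, a spindle protein, rose 11.7-fold (3.55 ± 0.54, adjusted p = 0.000682) and Cdc20, an activator of the anaphase-promoting complex, rose 9.53-fold (3.25 ± 0.49, adjusted p = 0.000682). Cdkn3, a phosphatase of cyclin-dependent kinases, rose by 3.11 ± 0.44 and the cyclin Ccnb1 by 3.06 ± 0.45, and Aspm, needed at spindle poles, rose by 2.97 ± 0.44. The kinase Cdk1 rose 5.15-fold (2.37 ± 0.34, adjusted p = 0.000492), and the mitotic motor Kif20a (2.49 ± 0.35) and the kinetochore protein Spc25 (1.70 ± 0.24) rose as well. Over the cell cycle list the camera test gave adjusted p = 4.09e-49, and adjusted p = 0.104 with an estimated correlation. Adjusted over the list alone, 37 of the 39 genes rose. Within slides 1, 2 and 3 the list's median was 1.90, 2.43 and 1.07. Of 22 p53 target genes, 3 rose and 0 fell (4 and 3 when adjusted over the list alone; camera adjusted p = 0.435). They were Psrc1, which binds microtubules (2.18 ± 0.34, adjusted p = 0.000743), Phlda3, an inhibitor of AKT signalling (0.94 ± 0.18, adjusted p = 0.00313), and the death receptor Tnfrsf10b (0.92 ± 0.22, adjusted p = 0.0208).

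Matrix and macrophage genes followed. Among 35 extracellular matrix genes, 12 rose and 0 fell (19 and 1 when adjusted over the list alone), with a median of 0.46 (camera adjusted p = 4.06e-15; adjusted p = 0.161 with an estimated correlation). Mmp12, the macrophage elastase, rose by 2.60 ± 0.38 (adjusted p = 0.000613) and was well above background on 1 WT control array, with a rise of 1.96 when the dim arrays were set to their floor. The collagen-binding proteoglycan Lum rose by 0.81 ± 0.15 (adjusted p = 0.00211) and the collagen chain Col6a3 by 0.97 ± 0.18 (adjusted p = 0.00294). The markers of recruited monocytes and macrophages held 6 that rose and 0 that fell among 17 (9 and 0 when adjusted over the list alone), with a median of 0.60 (camera adjusted p = 8.68e-10; adjusted p = 0.161 with an estimated correlation). Trem2, a lipid receptor of macrophages, rose 3.41-fold (1.77 ± 0.29, adjusted p = 0.00102) and the fractalkine receptor Cx3cr1 rose 2.47-fold (1.30 ± 0.29, adjusted p = 0.0121). Gpnmb, a glycoprotein of lipid-laden macrophages, was not well above background on any WT control array and on 1 WT FB1 array, so its rise (adjusted p = 0.00145) was at least 1.37-fold. This rested on WT FB1 replicate 1, without which the bound was -0.076 in log2 and gave no minimum fold. Neutrophil markers had 1 rise among 12 genes, Camp (1.45 ± 0.39), and 9 when adjusted over the list alone (camera adjusted p = 4.96e-07; adjusted p = 0.161 with an estimated correlation). Resident macrophage markers had 0 calls among 15 (camera adjusted p = 0.51), T and NK cell markers 0 among 13 (0.523), and sinusoidal endothelium markers 0 among 15 with a median of -0.34 (0.00125; adjusted p = 0.556 with an estimated correlation). Erythroid markers, also without a call among 10 genes, had a median of 0.52 (camera adjusted p = 0.00399; adjusted p = 0.476 with an estimated correlation). The WT controls themselves varied in these medians. Against the mean of the other 5, replicates 5 and 6 lay 0.78 and 1.24 higher in the cell cycle median and 1.33 and 1.03 higher in the erythroid median, while replicate 4 lay apart by -0.85 in the cell cycle median and -1.46 in the neutrophil median, and replicate 1 by -1.13 in the erythroid median. Without WT control replicates 4, 5 and 6 in turn, 452, 542 and 650 genes were called for FB1 in WT, and the cell cycle median was 1.59, 1.86 and 2.13.

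Lipid genes held few single calls. Me1, which supplies NADPH for fatty acid synthesis, fell by 0.81 ± 0.16 (adjusted p = 0.0054) and was the only call among 24 genes of fatty acid and triglyceride synthesis, whose median was -0.41 (camera adjusted p = 3.8e-06; adjusted p = 0.224 with an estimated correlation). Adjusted over the list alone the count was also 1. Among 25 cholesterol genes 1 fell, and 10 fell when adjusted over the list alone (median -0.50; camera adjusted p = 7e-08; adjusted p = 0.455 with an estimated correlation). Among 18 LXR target genes, lipoprotein lipase Lpl rose 3.30-fold (1.72 ± 0.27, adjusted p = 0.000743) and the phospholipid transfer protein Pltp fell (-0.60 ± 0.16, adjusted p = 0.0461), with the same counts when adjusted over the list alone (camera adjusted p = 0.359). Kdsr, the reductase of sphingolipid synthesis that acts before the ceramide synthases, rose 1.38-fold (0.46 ± 0.10, adjusted p = 0.00751). Its call was lost when its tested probes were averaged (adjusted p = 0.279), and over the sphingolipid list camera gave adjusted p = 0.419, with 1 gene also adjusted over the list alone. Of the ceramide synthase genes, Cers2, Cers4, Cers5 and Cers6 were tested and did not pass the test, with adjusted p from 0.346 to 0.941.

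Genes outside these lists fell too. The transcription factor Irx1 fell to below background on all 6 WT FB1 arrays, at least 1.55-fold from 5 measured WT control arrays (1.38 to 2.14 with 1 array left out; adjusted p = 0.000457). Mpped2, a metallophosphoesterase, fell by 2.12 ± 0.32 (1.89 with dim arrays at the floor; adjusted p = 0.000682), with 1 WT FB1 array well above background, and Slc22a3, an organic cation transporter, by 1.85 ± 0.32 (adjusted p = 0.00162). Cnn1, a smooth muscle calponin, fell by 2.55 ± 0.52 (adjusted p = 0.00612) and Bcl2l15 by 2.38 ± 0.48 (adjusted p = 0.00511). Of the xenobiotic genes, Cyp2b10 rose (1.37 ± 0.35, adjusted p = 0.03) and Cyp2c39 fell (-0.67 ± 0.18, adjusted p = 0.0481), each from a family of near-identical copies that a probe may not separate, and the list of 25 had the same counts when adjusted over the list alone (camera adjusted p = 0.0748). NRF2 target genes, a set induced by electrophiles, held 1 that rose and 2 that fell among 26, also adjusted over the list alone (camera adjusted p = 0.222). Osgin1 rose (1.23 ± 0.33, adjusted p = 0.0453), and G6pdx, the entry enzyme of the pentose phosphate pathway, fell (-0.53 ± 0.14, adjusted p = 0.0341). The median and mean of the p53 list and of the female-biased list differed in sign.

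The size of this response moved with single arrays, and a fit of the WT arrays alone called 381 genes. Without WT FB1 replicate 1, 386 genes were called and 77 of them were lower, and without WT FB1 replicate 4 the counts were 839 and 283. The lower genes numbered 93 without WT FB1 replicate 3, 115 without WT FB1 replicate 2 and 87 without WT control replicate 4. The calls of 7 genes (Camp, Cyp2b10, Cyp2c39, G6pdx, Osgin1, Pltp and Tnfrsf10b) were all lost without WT FB1 replicate 1, at adjusted p from 0.0529 to 0.135, and each was lost on leaving out any of 3 to 20 arrays. With slide as a block 645 genes were called, and 637 of the 638 kept their direction within each slide. Since the genes were called from the same slides together, their choice favours such counts, here and in the comparisons below.

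**Figure D2:**
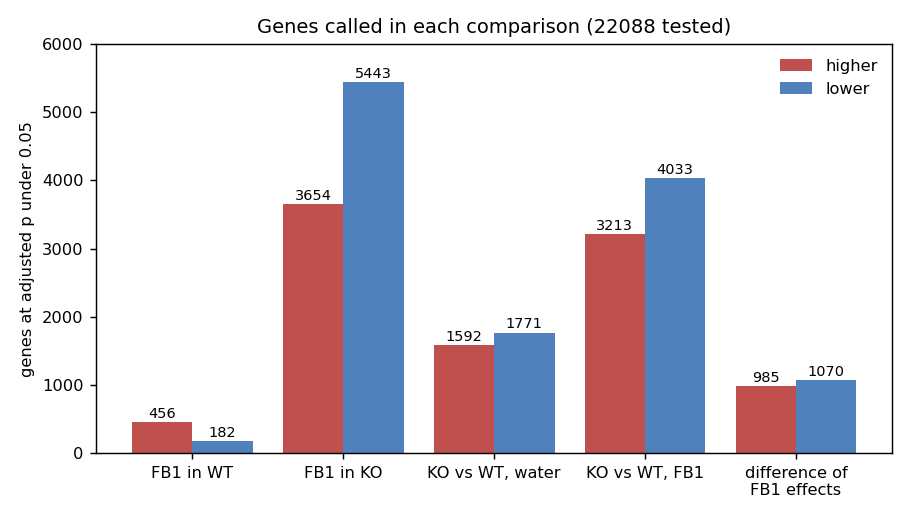
Number of genes higher (red) and lower (blue) at limma adjusted p under 0.05 in each of 5 comparisons, of 22088 tested. FB1 changed 638 genes in WT and 9097 in KO.

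FB1 in KO mice changed 9097 of 22088 genes (41.2%), 3654 higher and 5443 lower. The counts of list members called below stand against these shares of all genes. At 1.5-fold or more the balance was the other way, with 2101 higher and 1636 lower. The share of higher calls was 40.2%, and 48.8% with the authors' values. Most genes of the matrix, interferon, recruited macrophage and cell cycle lists were called higher, and most of the cholesterol, amino acid and xenobiotic lists lower, though each of these list calls was lost with an estimated correlation. The largest fall was that of Sult3a1, a female-biased sulfotransferase, by 7.23 ± 0.29 (151-fold, adjusted p = 1.61e-13). For the 43 genes named as called in this comparison, each of the 6 KO FB1 arrays lay beyond the mean of the KO controls, but these genes were chosen for being called. Over all genes with a value on every array of both groups, the groups did not overlap for 4050 of 22057 (18.4%, where chance gives 0.216%). With slide as a block the count was 9227, and 8871 of the 9097 genes kept their direction within each slide. That share is favoured by calling them from the same slides.

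Cell cycle genes rose in 37 of 39 cases and fell in 1, with the same counts when adjusted over the list alone, and a median of 2.08 (camera adjusted p = 3.24e-22; adjusted p = 0.203 with an estimated correlation). Kif20a rose 7.99-fold (adjusted p = 1.04e-06) and Ccnd1, the cyclin of the G1 phase, 4.17-fold (2.06 ± 0.25, adjusted p = 1.39e-06). In the extracellular matrix list 30 of 35 genes rose and 0 fell (31 and 0 when adjusted over the list alone), with a median of 1.46 (camera adjusted p = 3.24e-22; adjusted p = 0.162 with an estimated correlation). The calcium-binding annexin Anxa2 rose 6.32-fold (2.66 ± 0.24, adjusted p = 4.46e-08) and the gelatinase Mmp2 5.40-fold (2.43 ± 0.23, adjusted p = 1.04e-07). Stellate cell markers had 7 that rose and 1 that fell among 15, also when adjusted over the list alone (camera adjusted p = 0.00125; adjusted p = 0.203 with an estimated correlation), with Pdgfrb, a growth factor receptor of these cells, up by 0.95 ± 0.13 (adjusted p = 6.12e-06). Interferon response genes rose in 17 of 27 cases and fell in 0 (18 and 0 when adjusted over the list alone), with a median of 1.27 (camera adjusted p = 2.21e-09; adjusted p = 0.282 with an estimated correlation). Oas1a, an antiviral synthetase, rose 6.20-fold (2.63 ± 0.28, adjusted p = 4.11e-07) and Usp18, which removes ISG15, 3.45-fold (1.79 ± 0.22, adjusted p = 1.79e-06). Within slides 1, 2 and 3 the interferon median was 1.95, 0.52 and 1.14, and the matrix median 1.49, 1.095 and 1.56.

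Markers of cell types moved apart. Recruited monocyte and macrophage markers rose in 14 of 17 cases and fell in 0 (15 and 0 when adjusted over the list alone), with a median of 1.34 (camera adjusted p = 1.26e-11; adjusted p = 0.18 with an estimated correlation). Trem2 rose 7.30-fold (2.87 ± 0.29, adjusted p = 1.89e-07) and Ms4a7 4.36-fold (2.12 ± 0.24, adjusted p = 6.97e-07). Sinusoidal endothelium markers fell in 11 of 15 cases (13 when adjusted over the list alone), with a median of -0.58 (camera adjusted p = 0.000576; adjusted p = 0.353 with an estimated correlation), and the scavenger receptor Stab2 fell by 0.94 ± 0.13 (adjusted p = 7.72e-06). Among 15 resident macrophage markers 4 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.556), with the haemoglobin scavenger receptor Cd163 down by 2.15 ± 0.30 (adjusted p = 9.54e-06). Chemokine, cytokine and adhesion genes held 12 that rose and 3 that fell among 26, also when adjusted over the list alone (camera adjusted p = 0.000576; adjusted p = 0.282 with an estimated correlation), with the innate receptor Tlr2 up by 1.32 ± 0.21 (adjusted p = 3.54e-05). B and plasma cell markers rose in 5 of 8 cases, also adjusted over the list alone (camera adjusted p = 0.0204; adjusted p = 0.308 with an estimated correlation), with Jchain, which joins IgA and IgM units, up by 1.26 ± 0.22 (adjusted p = 0.000113). Cholangiocyte markers rose in 3 of 15 cases, also adjusted over the list alone, a share near the 3654 of 22088 for all genes (camera adjusted p = 0.0146; adjusted p = 0.282 with an estimated correlation). The ductal transcription factor Sox9 rose by 1.89 ± 0.27 (adjusted p = 1.2e-05). T and NK cell markers had 3 that rose and 1 that fell among 13 (2 and 1 when adjusted over the list alone; camera adjusted p = 0.0286; adjusted p = 0.483 with an estimated correlation). Neutrophil markers (2 rose and 1 fell of 12, camera adjusted p = 0.102), erythroid markers (1 fell of 10, 0.528) and pancreas and adipose markers (3 fell of 8, 0.352) gave no call as lists, with the same counts when adjusted over each list alone.

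Hepatocyte markers fell in 10 of 22 cases and rose in 0, also adjusted over the list alone, with a median of -0.11 (camera adjusted p = 0.00938; adjusted p = 0.483 with an estimated correlation). Among them were the glutamate transporter Slc1a2, down 37.6-fold (-5.23 ± 0.46, adjusted p = 3.9e-08) and glutamine synthetase Glul, down 4.36-fold (-2.13 ± 0.28, adjusted p = 4.69e-06). The list's mean of -0.51 lay below its median, and large falls such as these do not stand for the whole list. Fetal liver genes rose in 6 of 10 cases (camera adjusted p = 0.00301; adjusted p = 0.203 with an estimated correlation), with 6 that rose and 1 that fell when adjusted over the list alone. Dlk1, a Notch-family ligand of hepatoblasts, rose 27.8-fold (4.79 ± 0.43, adjusted p = 4.46e-08), the imprinted RNA H19 22.2-fold (4.47 ± 0.60, adjusted p = 5.21e-06) and alpha-fetoprotein Afp 2.66-fold (1.41 ± 0.24, adjusted p = 9.74e-05). The largest rises of all included Ly6d (5.75 ± 0.61, 53.9-fold, adjusted p = 3.44e-07) and the mucosal peptide Tff3 (4.03 ± 0.49, adjusted p = 1.83e-06), the latter from 3 KO control arrays well above background (3.84 with dim arrays at the floor).

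Many metabolic genes were lower in KO mice given FB1. Cholesterol synthesis and uptake genes fell in 23 of 25 cases (24 when adjusted over the list alone), with a median of -0.83 (camera adjusted p = 6.67e-07; adjusted p = 0.34 with an estimated correlation). Tm7sf2, a sterol reductase, fell by 1.43 ± 0.14 (adjusted p = 1.2e-07). Gluconeogenesis and amino acid catabolism genes fell in 23 of 26 cases and rose in 1, also adjusted over the list alone, with a median of -0.80 (camera adjusted p = 1.63e-08; adjusted p = 0.236 with an estimated correlation). Gnmt, which methylates glycine, fell by 1.04 ± 0.12 (adjusted p = 7.49e-07). Fatty acid and triglyceride synthesis genes fell in 12 of 24 cases (13 when adjusted over the list alone; camera adjusted p = 0.0127; adjusted p = 0.413 with an estimated correlation), including Thrsp, a lipogenic regulator (-2.66 ± 0.34, adjusted p = 3.24e-06). Xenobiotic enzymes fell in 18 of 25 cases and rose in 2, also adjusted over the list alone, with a median of -0.76 (camera adjusted p = 2.07e-05; adjusted p = 0.236 with an estimated correlation). Cyp2a5 fell by 1.40 ± 0.18 and Cyp2c50 by 1.25 ± 0.16, each a member of a family of near-identical copies. Bile acid genes fell in 13 of 21 cases and rose in 2, also adjusted over the list alone (median -0.50; camera adjusted p = 0.00206; adjusted p = 0.203 with an estimated correlation), with the steroid reductase Akr1d1 down by 1.39 ± 0.14 and the hydroxylase Cyp7b1 by 2.09 ± 0.19 (adjusted p = 4.28e-08). PPARα target genes fell in 10 of 28 cases, also adjusted over the list alone, without a call as a list (camera adjusted p = 0.0778).

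Sex-biased genes were lower in most calls. Female-biased liver genes fell in 11 of 18 cases and rose in 0 (13 and 0 when adjusted over the list alone), with a median of -1.06 (camera adjusted p = 7.31e-05; adjusted p = 0.203 with an estimated correlation). The Sult3a1 probe lies on chromosome 10 at 33599244 to 33599303 (mm9), and Sult3a2, a near-identical copy that cross-hybridisation may not separate, fell by 6.89 ± 0.37 (adjusted p = 3.71e-11). Cyp3a44, which also has near-identical copies, fell 7.92-fold (-2.99 ± 0.37, adjusted p = 2.43e-06). Male-biased liver genes had 4 that rose and 10 that fell among 17, also adjusted over the list alone (median -0.72; camera adjusted p = 0.188), and the complement gene C6 rose by 2.79 ± 0.28 (adjusted p = 1.58e-07).

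Stress lists rose in part. NRF2 target genes had 10 that rose and 2 that fell among 26 (14 and 2 when adjusted over the list alone; camera adjusted p = 0.00125; adjusted p = 0.203 with an estimated correlation), with the carbonyl reductase Cbr3 up by 1.35 ± 0.20 (adjusted p = 1.38e-05). The unfolded protein and integrated stress response had 7 that rose and 2 that fell among 26, also adjusted over the list alone (median 0.10; camera adjusted p = 0.0216; adjusted p = 0.34 with an estimated correlation), with asparagine synthetase Asns up 5.01-fold (2.32 ± 0.32, adjusted p = 6.83e-06). The p53 target genes had 10 that rose and 4 that fell among 22 (10 and 5 when adjusted over the list alone; median 0.07; camera adjusted p = 0.0323; adjusted p = 0.282 with an estimated correlation), with Psrc1 up 8.24-fold (3.04 ± 0.34) and Phlda3 3.42-fold (1.77 ± 0.18). Circadian clock genes had 1 that rose and 11 that fell among 19 (2 and 11 when adjusted over the list alone; camera adjusted p = 0.184), with Nr1d2 down by 1.38 ± 0.28 (adjusted p = 0.000466). Acute phase genes had 1 that rose and 4 that fell among 24 (0 and 2 when adjusted over the list alone; camera adjusted p = 0.337).

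Sphingolipid genes moved both ways in KO, with 9 that rose and 12 that fell among 35 (9 and 13 when adjusted over the list alone; camera adjusted p = 0.858). The ceramide synthase gene Cers5 rose (0.68 ± 0.09, adjusted p = 5.39e-06) and Cers2 fell (-0.57 ± 0.10, adjusted p = 9.61e-05), while Cers4 (-0.08 ± 0.10, adjusted p = 0.59) and Cers6 (-0.06 ± 0.10, adjusted p = 0.69) did not pass the test. Kdsr rose 1.79-fold (0.84 ± 0.10, adjusted p = 9.41e-07), and the neutral sphingomyelinase Smpd3 by more than any other of the list named here (3.59 ± 0.47, adjusted p = 3.81e-06). Among 18 LXR target genes 3 rose and 6 fell (3 and 7 when adjusted over the list alone; camera adjusted p = 0.758), with Lpl up 12.3-fold (3.62 ± 0.27, adjusted p = 5.73e-09) and the sterol transporter Abcg5 down by 1.46 ± 0.19 (adjusted p = 4.62e-06). The median, mean and test of the LXR, sphingolipid and resident macrophage lists did not all have the same sign. For 183 genes different probes passed the test in opposite directions.

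**Figure D3:**
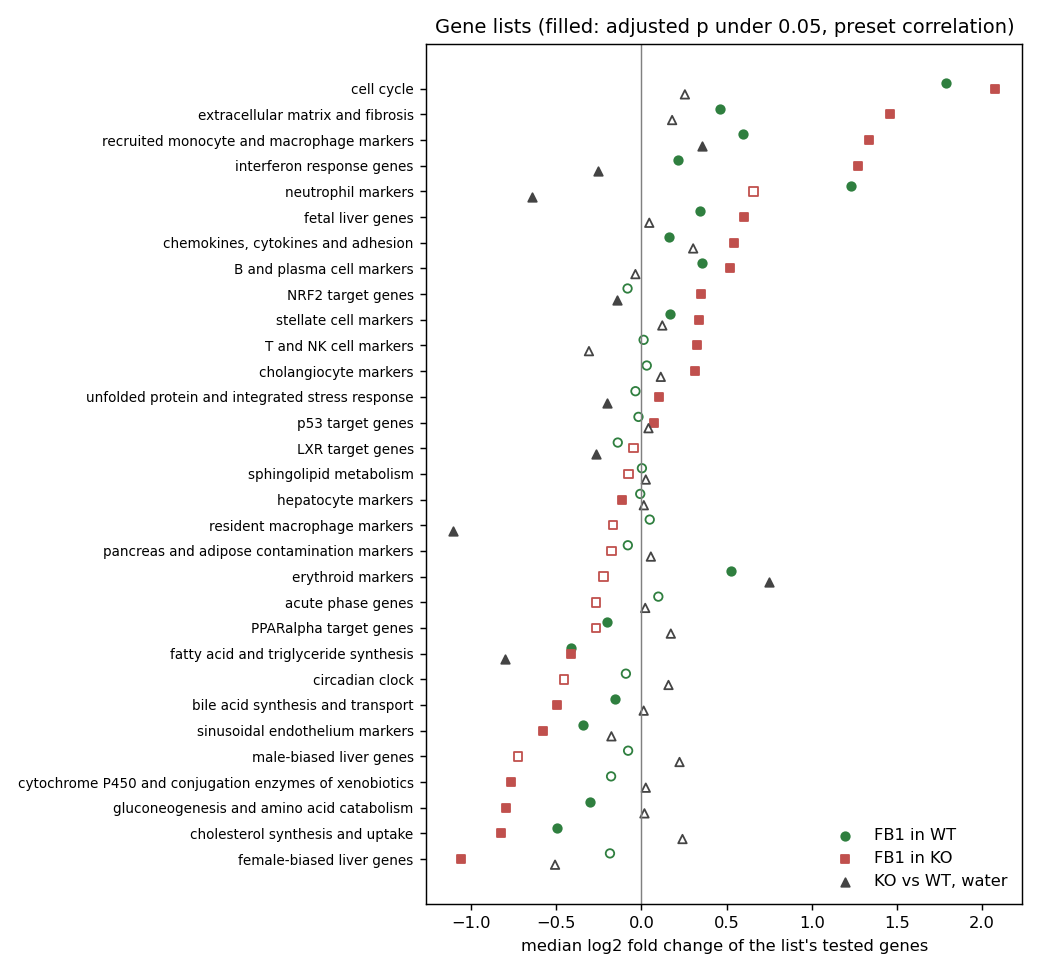
Median log2 fold change of each of 31 gene lists for FB1 in WT (circles), FB1 in KO (squares) and KO against WT without FB1 (triangles), filled where camera with a preset correlation gave adjusted p under 0.05. The cell cycle list has the highest median for FB1 in both genotypes, at 1.79 and 2.08.

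Whether FB1 acted differently in the 2 genotypes was tested as the difference of its log2 effects, KO minus WT. This difference passed the test for 2055 genes, 985 higher and 1070 lower, and at 1.5-fold or more for 728 higher and 576 lower. The change was larger in KO, in absolute size, for 1970 of them (95.9%), and 1908 were called in KO and not in WT. Higher differences included part of the matrix and interferon lists, and lower differences part of the female-biased, xenobiotic and amino acid lists, and each of these list calls was lost with an estimated correlation.

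The matrix list had 16 higher and 0 lower of 35 (25 and 0 when adjusted over the list alone), with a median difference of 0.71 (camera adjusted p = 9.32e-16; adjusted p = 0.162 with an estimated correlation). Among these were the collagen cross-linking enzyme Lox (2.40 ± 0.43, adjusted p = 0.00188), the growth factor Tgfb3 (1.71 ± 0.25, adjusted p = 0.000455) and Anxa2 (1.64 ± 0.34, adjusted p = 0.00456). Interferon response genes had 9 higher and 0 lower of 27 (15 and 0 when adjusted over the list alone; camera adjusted p = 6.32e-08; adjusted p = 0.433 with an estimated correlation), with Oas1a at 1.86 ± 0.40 and Usp18 at 1.47 ± 0.31. Their median was 0.99, and within slides 1, 2 and 3 it was 1.48, -0.095 and 1.54. Recruited macrophage markers had 6 higher and 0 lower of 17 (9 and 0 when adjusted over the list alone; camera adjusted p = 2.5e-06; adjusted p = 0.344 with an estimated correlation), including the lectin Lgals3 (1.48 ± 0.31) and lysozyme Lyz2 (1.08 ± 0.20), and within the 3 slides the median was 0.80, -0.014 and 1.54. NRF2 target genes had 6 higher and 0 lower of 26 (10 and 0 when adjusted over the list alone; camera adjusted p = 6.26e-06; adjusted p = 0.147 with an estimated correlation), with Cbr3 (1.24 ± 0.28) and G6pdx (0.96 ± 0.19). Asns (2.26 ± 0.45, adjusted p = 0.00384), Bax, a promoter of apoptosis (0.62 ± 0.11, adjusted p = 0.00249), Lpl (1.90 ± 0.38, adjusted p = 0.00391), Dlk1 (3.70 ± 0.61, adjusted p = 0.000958), H19 (3.52 ± 0.85, adjusted p = 0.0119) and Ly6d (4.19 ± 0.86, adjusted p = 0.00452) also had a higher FB1 effect in KO.

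Lower differences included those of Sult3a1 (-6.88 ± 0.41, adjusted p = 8.02e-10) and Slc1a2 (-3.89 ± 0.65, adjusted p = 0.00116). Female-biased genes had 5 lower and 0 higher of 18 (10 and 0 when adjusted over the list alone), with a median of -1.02 (camera adjusted p = 9.35e-07; adjusted p = 0.147 with an estimated correlation). Xenobiotic enzymes had 9 lower and 1 higher of 25 (12 and 2 when adjusted over the list alone; camera adjusted p = 2.31e-05; adjusted p = 0.344 with an estimated correlation), including Cyp2b10 (-2.50 ± 0.49, adjusted p = 0.00346) and Cyp2c54 (-1.16 ± 0.23, adjusted p = 0.00371), both from families of near-identical copies. Gluconeogenesis and amino acid genes had 7 lower and 0 higher of 26 (10 and 1 when adjusted over the list alone; camera adjusted p = 4.74e-06; adjusted p = 0.397 with an estimated correlation). Akr1d1 (-1.04 ± 0.20) and Tm7sf2 (-1.03 ± 0.20) fell more in KO, with 5 lower and 1 higher of 21 bile acid genes (9 and 2 when adjusted over the list alone) and 2 lower and 0 higher of 25 cholesterol genes, also adjusted over the list alone (camera adjusted p = 0.00673 for each; adjusted p = 0.344 and 0.611 with an estimated correlation). Cell cycle genes held 1 call of 39, also adjusted over the list alone. It was thymidine kinase Tk1 (-1.32 ± 0.26, adjusted p = 0.00389), while the list's median was 0.32 (camera adjusted p = 0.0135; adjusted p = 0.657 with an estimated correlation). Among the ceramide synthases, Cers5 differed (0.66 ± 0.13, adjusted p = 0.00336), Cers2 differed narrowly (-0.47 ± 0.14, adjusted p = 0.0378), and Cers4 (adjusted p = 0.963) and Cers6 (adjusted p = 0.635) did not pass the test. The call of Cers2 was lost on leaving out any of 15 arrays, with adjusted p up to 0.0709. Smpd3 had a higher effect in KO (3.09 ± 0.66, adjusted p = 0.0058). The LXR, sphingolipid and resident macrophage lists had a median, mean and test that differed in sign.

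Over all tested genes the log2 effects of FB1 in WT and KO correlated across genes at Pearson r = 0.621 and Spearman rho = 0.531, where genes are not independent replicates, and without the filter on dim probes r was 0.415 and 1258 genes differed. Of the 638 genes called in WT, 390 were higher and 121 lower in both genotypes, against 75.4 and 44.8 for independent lists, and 5 were called in opposite directions. The difference itself passed the test for 111 of the 638. Leaving out KO FB1 replicate 3 raised the count of differences to 3038, with 1763 lower, and leaving out KO FB1 replicate 1 gave 1490, with 756 lower. The share of higher calls was 47.9%, but 52.4% with quantile normalisation and 58.2% with the authors' values. With slide as a block 2111 genes were called, and 2005 of the 2055 kept their direction within each slide, from which they had been called.

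**Figure D4:**
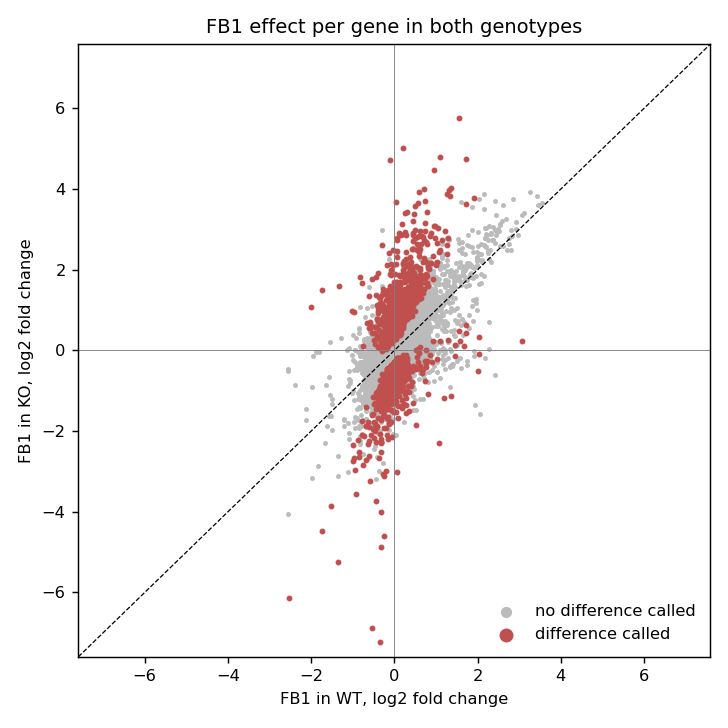
Log2 fold change by FB1 in WT (x axis) and in KO (y axis) for each of 22088 genes, with genes whose effects differ at adjusted p under 0.05 in red and the line of equal effects dashed. Of the 2055 red genes, 1970 changed more in KO in absolute size.

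Mice given water showed how KO and WT livers differed without FB1. Loss of the receptors cannot be told apart here from other differences between the genotypes, such as strain background. KO livers had lower levels of some LXR target genes and of most lipogenic genes and resident macrophage markers listed, with higher levels of some recruited macrophage markers and of the Cyp2b genes named below. Of 22088 genes 3363 differed, 1592 higher and 1771 lower in KO, and 1831 by at least 1.5-fold. The share of higher calls was 47.3%, and 51.5% with quantile normalisation. For the 38 genes named as called in this comparison, Rian and Mirg included, each of the 6 KO arrays lay beyond the mean of the WT controls, but these genes were chosen for being called. Over all genes with a value on every array of both groups, the groups did not overlap for 1750 of 22060 (7.93%, where chance gives 0.216%). With slide as a block the count was 3403, and 3333 of the 3363 kept their direction within each slide. Here too the genes had been called from these slides.

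LXR target genes were lower for 8 of 18 and higher for 0 (9 and 0 when adjusted over the list alone), with a median of -0.27 (camera adjusted p = 9.9e-06). This was the only list call of any comparison that held with an estimated correlation (adjusted p = 0.00546). Stearoyl-CoA desaturase Scd1 was 18.7-fold lower (-4.22 ± 0.27, adjusted p = 3.19e-11), Pltp 5.05-fold lower (-2.34 ± 0.16, adjusted p = 1.83e-10) and Lpl 3.14-fold lower (-1.65 ± 0.27, adjusted p = 9.75e-05). Fatty acid and triglyceride synthesis genes, a list that shares Scd1, Fasn and Srebf1 with the LXR list, were lower for 14 of 24 (16 when adjusted over the list alone), with a median of -0.80 (camera adjusted p = 6.79e-10; adjusted p = 0.122 with an estimated correlation). The acetyl-CoA carboxylase Acacb was 9.59-fold lower (-3.26 ± 0.28, adjusted p = 7.11e-09) and Me1 2.43-fold lower (-1.28 ± 0.16, adjusted p = 3.85e-06).

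Resident macrophage markers were lower for 11 of 15 (14 lower and 1 higher when adjusted over the list alone), with a median of -1.104 (camera adjusted p = 3.04e-14; adjusted p = 0.122 with an estimated correlation). Cd5l, a secreted scavenger-family protein of macrophages, was 574-fold lower (-9.16 ± 0.28, adjusted p = 3.09e-17), Cd163 13.1-fold (-3.72 ± 0.30) and the Kupffer cell lectin Clec4f 6.33-fold (-2.66 ± 0.19, adjusted p = 2.69e-10). The lectin Cd209f was lower by 6.96 ± 0.35 (6.67 with dim arrays at the floor; adjusted p = 6.63e-13), with 2 of the KO arrays well above background. Recruited macrophage markers were higher for 7 of 17 and lower for 4 (9 and 4 when adjusted over the list alone; camera adjusted p = 0.0137; adjusted p = 0.954 with an estimated correlation), and within slides 1, 2 and 3 the median was 0.55, 1.16 and -0.17. Cx3cr1 was 11.3-fold higher (3.50 ± 0.29, adjusted p = 3.72e-09), the integrin Itgax 4.89-fold higher (2.29 ± 0.22), and Gpnmb, not well above background on any WT control array, at least 30.3-fold higher (adjusted p = 6.86e-12). Chemokine genes were higher for 9 of 26 and lower for 3, also adjusted over the list alone (camera adjusted p = 0.0898), and the chemokine Ccl3 was at least 3.78-fold higher (adjusted p = 2.82e-08). The metalloproteinases Mmp12 (3.08 ± 0.38; 2.44 with dim arrays at the floor) and Mmp13 (4.70 ± 0.55; 3.57 with dim arrays at the floor), each well above background on 1 WT control array, were higher within a matrix list that had 4 higher and 2 lower of 35, also adjusted over the list alone (camera adjusted p = 0.0796).

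Cytochrome P450 genes differed in both directions, with 4 higher and 5 lower of 25 xenobiotic genes (4 and 6 when adjusted over the list alone; camera adjusted p = 0.895). Cyp2b10 was 508-fold higher (8.99 ± 0.35, adjusted p = 4.04e-15), Cyp2b9 1391-fold higher (10.44 ± 0.42, adjusted p = 1.03e-14), and Cyp2b13 higher by 12.64 ± 0.54 (11.80 with dim arrays at the floor), with 2 WT control arrays well above background. Their probes lie on chromosome 7 (mm9), starting at 26711522, 26995607 and 26880905, and these near-identical copies may share hybridisation. Cyp2c39 was 26.7-fold higher (4.74 ± 0.18, adjusted p = 4.04e-15) and Cyp2c55 6.06-fold lower (-2.60 ± 0.37), in a family with the same limit. Cyp2b9 and Cyp2b13 are female-biased, and were the 2 genes higher in that list of 18, where 3 were lower (2 and 6 when adjusted over the list alone; camera adjusted p = 0.379), Cyp2a4 among them (-1.47 ± 0.17). NRF2 target genes were lower for 5 of 26, also adjusted over the list alone (camera adjusted p = 0.0137; adjusted p = 0.672 with an estimated correlation), with the haem oxygenase Hmox1 (-1.86 ± 0.30) and G6pdx (-1.02 ± 0.14). The unfolded protein list was lower for 5 of 26, also adjusted over the list alone (camera adjusted p = 0.0117; adjusted p = 0.672 with an estimated correlation), with Asns at -1.59 ± 0.32 (adjusted p = 0.00102). Neutrophil markers were lower for 3 of 12 (6 when adjusted over the list alone; camera adjusted p = 0.0245; adjusted p = 0.954 with an estimated correlation), with Mpo at -2.21 ± 0.54 (adjusted p = 0.0064). Erythroid markers had 1 higher of 10 (7 when adjusted over the list alone; camera adjusted p = 0.0117; adjusted p = 0.954 with an estimated correlation), and interferon genes had 1 higher and 2 lower of 27, also adjusted over the list alone (camera adjusted p = 0.0432; adjusted p = 0.954 with an estimated correlation). Acute phase genes had 3 higher and 2 lower of 24, also adjusted over the list alone (camera adjusted p = 0.934), with the amyloid protein Saa3 higher (2.21 ± 0.30) and Crp lower (-1.74 ± 0.23).

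The sphingolipid list had 3 higher and 4 lower of 35 (4 and 4 when adjusted over the list alone; camera adjusted p = 0.895). Sphingosine kinase Sphk1 was higher (1.23 ± 0.19, adjusted p = 4.36e-05), as was the ceramidase Asah1 (0.56 ± 0.09, adjusted p = 8.04e-05). Cers6 was lower (-0.40 ± 0.10, adjusted p = 0.00889), a call lost when its tested probes were averaged (adjusted p = 0.148), and Cers2, Cers4 and Cers5 did not pass the test (adjusted p from 0.587 to 0.661). Outside the lists, Wdr72 was below background on every KO control array and at least 39.4-fold lower (adjusted p = 2.29e-12), and Ren2 was 108-fold lower (-6.75 ± 0.35, adjusted p = 7.36e-13). The Ren2 probe has no mm9 position here, and a strain difference in its DNA was not told apart from one in expression. Sntg1, below background on every WT control array, was at least 18.2-fold higher (adjusted p = 1.77e-11), and the imprinted RNA Meg3 was 35.2-fold higher (5.14 ± 0.36, adjusted p = 2.52e-10). The bile acid, acute phase, gluconeogenesis, female-biased, fetal, hepatocyte and pancreas lists had a median, mean and test that differed in sign, and 65 genes had probes called in opposite directions.

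Between KO and WT mice given FB1, 7246 genes differed, 3213 higher and 4033 lower in KO, and 3255 by at least 1.5-fold. The share of higher calls was 44.3%, but 50.6% with quantile normalisation and 52.6% with the authors' values, so that the direction of the balance depended on the scaling. The matrix list was higher for 31 of 35 and lower for 1 (32 and 1 when adjusted over the list alone), with a median of 0.99 (camera adjusted p = 6.07e-17; adjusted p = 0.196 with an estimated correlation). Female-biased genes were lower for 15 of 18 and higher for 2, also adjusted over the list alone, with a median of -1.64 (camera adjusted p = 0.000144; adjusted p = 0.231 with an estimated correlation). Recruited macrophage markers were higher for 12 of 17 and lower for 2, also adjusted over the list alone (camera adjusted p = 1.78e-07; adjusted p = 0.231 with an estimated correlation). Resident macrophage markers were lower for 10 of 15 and higher for 1, also adjusted over the list alone (camera adjusted p = 2.72e-06; adjusted p = 0.417 with an estimated correlation). LXR target genes were lower for 12 of 18 and higher for 1, also adjusted over the list alone (camera adjusted p = 0.000682; adjusted p = 0.0674 with an estimated correlation), and fatty acid synthesis genes lower for 16 of 24 and higher for 1, also adjusted over the list alone (camera adjusted p = 5.67e-07; adjusted p = 0.231 with an estimated correlation). The sphingolipid list had a median, mean and test that differed in sign. With slide as a block 7346 genes were called, and 6989 of the 7246 kept their direction within each slide, again the slides that gave the calls.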

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

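The tests of the spread between replicates, the hepatocyte share, hepatocyte transcripts and the male pattern were chosen only after the result was seen, while the splits of the arrays and the search for 1 unusual array were set before, and the limits over drawn members and the separate test of part of the male-biased genes were added last, with the other values of these tests known. FB1 changed 638 genes in WT and 9097 in KO, and the difference itself passed the test for 2055. For each comparison 1 of 100 splits, the real one, gave as many genes. This is the smallest share that 100 splits can give, so a chance origin of the counts is argued against but not excluded. Over genes with a value on every array, the real and the highest other counts were 637 and 201 for FB1 in WT, 9077 and 4185 for FB1 in KO, 3354 and 885 for KO against WT without FB1, and 7224 and 3804 with FB1. For the difference of effects, where residuals of an additive fit were reordered, they were 2052 and 731.

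More genes changed by FB1 in KO than in WT. A smaller spread between replicates in KO could not by itself give more calls, since the fit shares 1 spread per gene over all arrays. The median SD was 0.212 in WT control, 0.188 in WT FB1, 0.175 in KO control and 0.206 in KO FB1 arrays. The SD of the fold changes beyond their error was 2.03 times as large in KO (1.84 to 2.20 with 1 array left out). This restates that the effects were larger in KO. A single unusual WT array is argued against because leaving out 1 array raised the WT count to at most 839, without WT FB1 replicate 4, against at least 7976 in KO. A lower share of hepatocytes as the only change in cell makeup would raise the markers of other cells alike. This is argued against, since the medians of monocyte and sinusoidal endothelium markers differed by 1.92 (1.85 to 2.11 with 1 array left out; 95% limits over members drawn as if independent 1.65 to 2.25). It cannot exclude a lower share of hepatocytes beside other changes in cell makeup, and hepatocyte markers were lower for 10 of 22 and higher for 0. A stronger response to FB1 in the KO mice may be a biological difference, as a hypothesis found and tested on the same data. The part that cell makeup has in it stays open. Loss of the receptors cannot be told apart here from other differences between the genotypes, such as strain background, as its source.

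Of 18 female-biased liver genes 11 were called lower with FB1 in KO and 0 higher, a shift of the list by camera (adjusted p = 7.31e-05) that was lost with an estimated correlation (adjusted p = 0.203). A general loss of hepatocyte transcripts is argued against by a difference of -0.95 between their median and that of hepatocyte markers (-1.098 to -0.88 with 1 array left out; 95% limits over drawn members -1.53 to -0.54). A shift of the male-biased genes as a whole to the male pattern is argued against, narrowly, by their median of -0.72 (-0.91 to -0.62 with 1 array left out; 95% limits over members drawn as if independent -1.75 to -0.033), although camera did not call the list (adjusted p = 0.188, and adjusted p = 0.577 with an estimated correlation). A shift of part of the male-biased genes stays open, since 4 of the 17 were called higher, C6 by 2.79, and 10 lower, and the share called higher (23.5%, against 16.5% of other genes) did not differ past the threshold (one-sided Fisher's exact p = 0.306). An effect on female-biased genes beyond that on hepatocyte markers may remain, and its cause was not tested. It need not be specific to them, since cholesterol, amino acid, xenobiotic and male-biased lists also had negative medians and a difference from them was not tested.

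The FB1 effect differed between genotypes, KO minus WT, for 27 genes named here. Higher differences were 0.66 for Cers5, 3.09 for Smpd3, 2.40 for Lox, 1.71 for Tgfb3, 1.64 for Anxa2, 1.86 for Oas1a, 1.47 for Usp18, 1.48 for Lgals3, 1.08 for Lyz2, 1.24 for Cbr3, 0.96 for G6pdx, 2.26 for Asns, 0.62 for Bax, 3.52 for H19, 3.70 for Dlk1, 4.19 for Ly6d and 1.90 for Lpl. Lower differences were -0.47 for Cers2, -6.88 for Sult3a1, -2.50 for Cyp2b10, -1.16 for Cyp2c54, -1.04 for Akr1d1, -1.03 for Tm7sf2, -3.89 for Slc1a2, -1.32 for Tk1, -2.51 for Meg3 and -1.69 for Mirg. The call of Cers2 was lost on leaving out any of 15 arrays, with adjusted p up to 0.0709.

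List medians of this difference, each past the threshold with the preset correlation and not with an estimated correlation, were higher for 11 lists. They were 0.99 for interferon, 0.74 for recruited macrophages, 0.71 for matrix, 0.42 for NRF2, 0.34 for fetal genes, 0.33 for the unfolded protein response, 0.32 for cell cycle, 0.25 for T and NK cells, 0.23 for cholangiocytes, 0.21 for p53 and 0.19 for chemokines. The 9 lower medians were -1.02 for female-biased genes, -0.81 for erythroid markers, -0.52 for xenobiotic enzymes, -0.52 for gluconeogenesis and amino acid genes, -0.35 for cholesterol, -0.34 for acute phase, -0.31 for bile acids, -0.30 for sinusoidal endothelium and -0.15 for hepatocytes.

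Single arrays lay apart from the other 5 of their group, by a gap to the nearest above the 95% critical share of the group's range (Dixon), in 29 of 424 groups (6.84%), where chance gives about 1 in 20. WT control replicate 4 was apart for 7 genes, with ratios of 0.689 for Cers2 (4.25 against a mean of 3.80), 0.723 for Clec4f (4.0003 against 4.75), 0.676 for Cnn1 (-0.51 against -3.44), 0.702 for Hmox1 (1.71 against 3.85), 0.759 for Lox (-3.99 against -5.29), 0.636 for Ms4a7 (-3.59 against -2.60) and 0.657 for Slc1a2 (3.54 against 3.03). WT FB1 replicate 1 was apart for 6, at 0.689 for Bcl2l15 (-2.40 against -4.93), 0.763 for Cers6 (1.85 against 2.02), 0.632 for Col6a3 (0.57 against -0.026), 0.661 for Gpnmb (-2.79 against -5.95), 0.667 for Lum (1.83 against 1.06) and 0.667 for Phlda3 (0.49 against -0.48). WT control replicate 6 was apart for Ccl3 (0.712), Cyp2c50 (0.711), Ly6d (0.667) and Pltp (0.660), and WT FB1 replicate 2 for C6 (0.727), Clec4f (0.746) and Lyz2 (0.6254). KO FB1 replicate 5 was apart for Cyp2c39 (0.667) and Scd1 (0.844), and KO FB1 replicate 6 for Cyp2b13 (0.730) and Nr1h3 (0.704). In that array both Nr1h3 probes were higher, at -2.56 and -3.19, against -5.12 to -4.37 and -5.24 to -4.77 in the other 5. Of 18 other genes at least 4 lower in KO with and without FB1, a choice made after these values were seen, 8 were highest of the KO FB1 arrays in replicate 6, Wdr72 among them (-4.88 against -8.16 to -6.16), where chance gives 16.7% of genes. Others of the 18 were not raised there, such as Pcolce2 (-7.41 against -6.74 to -5.48) and Cd209f (-7.92 against -8.06 to -6.28). Both were not well above background on any KO FB1 array. Carry-over of RNA from a WT mouse would raise all 18, so the values go both ways and carry-over is neither shown nor excluded. Without this array 8097 genes were called for FB1 in KO. The remaining ratios were 0.779 for Irx1 in WT control replicate 2, 0.646 for Scd1 in WT control replicate 1, 0.666 for Hmox1 in KO FB1 replicate 3 and 0.665 for Stab2 in KO FB1 replicate 1. On the third principal component WT control replicate 5 lay at -63.3, against a mean of 3.997 for the other WT controls, a ratio of 0.811.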

How the results depend on the processing

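All alternatives reported here were planned. Of 143 called results of named genes, 126 stayed called at adjusted p under 0.05 under every alternative fit that tested them, 137 were at least 1.5-fold and 132 had adjusted p under 0.01, and 1 of 23 not called became so, Rian for FB1 in WT with the mean of probes (adjusted p = 0.0354) and without WT FB1 replicate 5 (0.0368). Named genes were a selection and more stable than all genes the naming rule allows, where 63 of 305 calls were lost in at least 1 alternative, 37 of them on leaving out 1 array, and 7 turned direction. For FB1 in WT 22 of 42 such calls were lost, against 6 of 102 for FB1 in KO, 16 of 89 for genotype without FB1 and 19 of 72 for the difference of effects. In fits of the compared groups alone 12 named calls were lost, all for FB1 in WT. They were Camp, Cyp2b10, Cyp2c39, G6pdx, Osgin1, Pltp, Tnfrsf10b, Gpnmb, Cnn1, Me1 (adjusted p = 0.0803), Cx3cr1 (0.0983) and Bcl2l15 (0.0777). Among named WT calls, Col6a3 (0.155) and Kdsr (0.279) were lost with the mean of probes, and Gpnmb (up to 0.136) and Cnn1 (up to 0.0672) in 3 and 2 alternatives, by limma. Of 84 list calls, 1 was never lost.

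Called genes numbered 417, 3737, 1831, 3255 and 1304 at 1.5-fold or more, for FB1 in WT, FB1 in KO, KO against WT without FB1, with FB1, and the difference of effects. At adjusted p under 0.01 they were 279 for FB1 in WT, 1917 and 4699 between genotypes and 624 for the difference, fewer by construction. With the WT arrays alone 381 genes were called, a fit with fewer arrays. Without the filter on dim probes the difference had 1258 genes, KO against WT without FB1 had 14 list calls, and the correlation of FB1 effects was 0.415, and the cause was not tested. Over genes called in at least 1 genotype that correlation was 0.721. With an estimated correlation the list calls were 0, 0, 1, 0 and 0.

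Leaving out each array gave 386 (without WT FB1 replicate 1) to 839 (without WT FB1 replicate 4) genes for FB1 in WT, 7976 to 9794 for FB1 in KO, 2828 to 3538 and 6191 to 7854 between genotypes, and 1490 (without KO FB1 replicate 1) to 3038 (without KO FB1 replicate 3) for the difference. List calls ranged over 12 to 18, 19 to 22, 8 to 12, 16 to 19 and 15 to 21, and the correlation over 0.566 to 0.632. The groups share replicate numbers, but these did not pair the mice. Deviations of same-numbered arrays correlated at -0.20 to 0.24, 5 of 36 pairs above 0.1, and 2 of 24 arrays correlated best with their own number. With the replicate number as a block the counts were 552, 8912, 3190, 6994 and 1898.

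Within a single slide, with 2 arrays per group and no test, 19 medians of called lists changed sign, and the cause was not tested. In slide 1 they were -0.053 for the unfolded protein response in FB1 in KO and -0.061 for cell cycle between genotypes with FB1. In slide 2 they were 0.041 for hepatocytes and -0.10 for T and NK cells in FB1 in KO, and -0.021 for p53 and -0.12 for interferon between genotypes with FB1. For the difference in slide 2 they were 0.058 for cholesterol, -0.22 for cell cycle, -0.18 for chemokines, -0.095 for interferon, -0.017 for fetal genes, -0.014 for recruited macrophages and -0.014 for T and NK cells. In slide 3 they were 0.028 for bile acids, -0.33 for chemokines, -0.35 for interferon, 0.16 for PPARα targets and 0.15 for sinusoidal endothelium in FB1 in WT, and -0.17 for recruited macrophages between genotypes without FB1. Signal over background limits genes near the floor, and setting those to their bounds moved a list median by at most 0.14.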

Other observations

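The test of LXR target genes was chosen only after the result was seen, and that of DNA near the deleted genes before. Noncoding RNAs of an imprinted cluster on chromosome 12 (mm9), expressed from the maternal copy, differed between genotypes. Meg3 (110809678 to 110809737) was higher in KO than WT without FB1 by 5.14 ± 0.36 (limma adjusted p = 2.52e-10), Rian (110899840 to 110899899) by 3.69 ± 0.43 (adjusted p = 9.39e-07) and Mirg (110987569 to 110987628) by 4.07 ± 0.30 (adjusted p = 4.14e-10). Rian and Mirg were chosen after their values were seen. Dlk1, a paternally expressed gene of the same cluster, did not pass the test between these groups (0.61 ± 0.43, adjusted p = 0.392). FB1 raised Meg3 (2.0003 ± 0.36, adjusted p = 0.00244) and Mirg (2.02 ± 0.30, adjusted p = 0.000613) in WT, while Rian did not pass the test (1.35 ± 0.43, adjusted p = 0.0911; 0.0368 without WT FB1 replicate 5). In KO the values were -0.51 for Meg3 (adjusted p = 0.277), 0.33 for Mirg (adjusted p = 0.39) and 0.48 for Rian (adjusted p = 0.391), and Dlk1 rose by 4.79 ± 0.43. The difference of the FB1 effects passed the test for Meg3 (-2.51 ± 0.52, adjusted p = 0.00456) and Mirg (-1.69 ± 0.42, adjusted p = 0.0146; 0.151 with normexp background correction and 0.0981 with the authors' values), and for Rian it was -0.87 (adjusted p = 0.403).

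Genotype differences of at least 1 in log2 were called the same way with and without FB1 for 674 genes. If DNA of another strain carried along beside the deleted genes were their source, such genes should be denser within 20 Mb of Nr1h3 or Nr1h2. The deleted genes and genes without a position, Ren2 among the latter, were left out of this test. Such genes made up 21 of 615 genes there and 642 of 21318 elsewhere, a ratio of 1.13 (95% limits 0.740 to 1.74, one-sided Fisher's exact p = 0.314), which leaves this explanation open because the limits include both no excess and a moderate excess. By region they were 13 of 309 near Nr1h3 and 8 of 306 near Nr1h2. Cyp2b9, Cyp2b10 and Cyp2b13, on the chromosome of Nr1h2 but outside the 20 Mb, counted as elsewhere. Loss of the receptors may account for the part in LXR target genes, whose list was lower in KO controls with an estimated correlation (adjusted p = 0.00546). Whether strain background differed elsewhere in the genome was not tested.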
